A study of Homo sapiens with 4 samples.

How the data were processed

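Polyadenylated RNA was sequenced from 4 libraries of CAL27 cells, 2 of the negative control and 2 with CCL20 overexpression, harvested after 48 hours, with 1.5 µg of RNA per library, per the labels' protocols. The submitters' processing notes name HISAT2 without a version, HTSeq 0.13.5 and the build GRCh38; the annotation, read trimming and strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. Each deposited table holds, per the file headers, a count and an FPKM value for 29437 genes. The counts deposited by the authors are whole reads per gene, not normalized. The FPKM values deposited by the authors are the count divided by a gene length and by that library's total count; the lengths implied by them were whole numbers for all 29437 genes within 0.0001 nt, and 99.7% equal the union exon length in GENCODE 29. All 29437 identifiers and names matched GENCODE 29, which was used for gene type, position and transcript length.

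Total counts lay between 13681862 and 17860695 per library, and genes with a read numbered 24747 and 24923 in the control libraries and 22378 and 21433 in the overexpression libraries. Replicates were compared before they were averaged. The chi-square of counts per gene was 7.18 in the control pair and 41.51 in the overexpression pair, above sampling noise in both, so no library was counted as a duplicate. Groups and replicate numbers come from the labels. The floor for a gene without counts covers counting error only.

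The design fixed before the data were examined foresaw limma on log2(FPKM + 1), or edgeR if the tables held counts. Since they held counts, the main test was edgeR 4.0.16 (R 4.3.3; glmQLFit and glmQLFTest, TMM factors, two-sided, Benjamini-Hochberg adjustment), on 12168 genes with a mean FPKM of at least 1, with a threshold of 0.05. The SE of a log2 fold change was taken from the fold change and its F statistic. limma 3.58.1 and DESeq2 1.42.0 served as alternatives. The 36 gene lists were fixed at the same time, and 33 with at least 5 tested members were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2. The genes named are CCL20 and CCR6, the 12 coding genes with the largest rise and the 12 with the largest fall among named genes past the threshold whose groups did not overlap, up to 4 members of each list past its threshold by test statistic, up to 2 of the highest members of each other list, and the highest marker of each other cell type. Groups did not overlap for 8847 of the tested genes, 72.7%, where chance gives 33.3%. Overlap was judged on counts scaled by total count, without the TMM factors. These were 1.08 and 1.07 in the control libraries and 0.97 and 0.90 in the overexpression libraries. A shift in scale between groups can by itself separate genes, so the excess over 33.3% does not measure separation on the scale of the test. CALR, for example, was counted as lower with overexpression, while its edgeR log2 fold change was 0.036.

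Alternatives fixed before the data were seen were other pseudocounts, filters, scalings, variance models, thresholds and set tests, a replicate block, and leaving out each library in turn. Added after seeing the data were limma on log2(FPKM + 1), edgeR's own filter, coding genes only, and 7 corrections for length. Each takes the deviation of log2 CPM from the gene mean in each library, fits a natural spline with 5 degrees of freedom, and uses the fit as an offset. The first used exonic length over all gene types, alone or with gene span and GC content. The next used coding genes and the longest principal transcript; it was replaced by the median of the principal transcripts because it gave ribosomal protein genes lengths above those of their usual mRNAs. The last is the mRNA length correction named in the results. It was chosen after its calls had been seen, and the 7 corrections gave between 721 and 4515 genes. The annotated principal transcript is not always the one expressed, and the correction leaves a Spearman correlation of -0.17 with mRNA length over coding genes with a mean FPKM of at least 20.

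List medians were compared with 10000 random lists of coding genes matched on mRNA length and mean FPKM (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, Python 3.11.15). For ribosomal protein and oxidative phosphorylation genes this was done with all members and with members under 1200 nt, and with the rest of the gene family in or out of the pool. In counts simulated from the means and sizes of these libraries, with no length trend over 12168 genes, edgeR recovered 61% of 2-fold and 99% of 4-fold changes, with 3% of its calls false. With a simulated trend in exonic length, which the correction then used, 89.3% of the uncorrected calls and 4% of the corrected calls were false. These simulations gave all genes and libraries the same dispersion and put a straight trend only between the groups. In the data the overexpression pair varied more than the control pair (chi-square per gene 41.51 against 7.18). The simulated rates are therefore not error rates of the calls here. The matched lists were tested on 200 simulated lists of 20 genes over 10572 coding genes with the measured slope on mRNA length: 3.0% lay above the upper limit of the central range with no shift and 95.0% with a log2 shift of 0.5. The simulated members were random genes with shuffled residuals, so they were independent of each other. These rates do not cover lists whose members vary together, such as ribosomal proteins, with an estimated correlation of 0.586.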

Results

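RNA sequencing was used to compare CAL27 cells labelled as overexpressing CCL20 with negative control cells, and the groups are named here by these labels. CAL27 is an established human oral squamous cell carcinoma line, and CCL20 is a secreted chemokine that attracts immune cells carrying the receptor CCR6. Per the labels the overexpression line was made with a lentivirus, and the comparison asks which genes differ in expression when CCL20 is overexpressed. There were 4 libraries of polyadenylated RNA, 2 from each group. Total gene counts were 13681862 and 17860695 in negative control replicates 1 and 2, and 15355030 and 16870325 in CCL20-overexpression replicates 1 and 2. Nothing in the labels says that the replicates came from separate cultures, so the edgeR p-values rest on the spread between these libraries. The camera p-values at the preset correlation compare list members with the other genes, and they do not measure that spread.

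CCL20 (ENSG00000115009; GRCh38 chromosome 2, 227805739 to 227817564, plus strand, a protein-coding gene with an mRNA of 800 nt) was measured as the check of the labels. Its level was 7.86 ± 1.08 FPKM in the negative control and 13.2 ± 2.78 FPKM with overexpression (SD, n = 2 each). The counts were 188 and 202 in the control libraries and 372 and 303 in the overexpression libraries. This was a rise of 1.94-fold (log2 fold change 0.95, SE 0.21, edgeR adjusted p = 0.0143), with both overexpression libraries above both controls. Fold changes here and below are edgeR estimates on TMM-scaled counts and differ from the ratios of the FPKM means, which are scaled by total count. There were 845 of 10572 tested coding genes with a larger log2 fold change, and CCL20 lay at the percentile of 31.0 among the 200 coding genes nearest in mRNA length. Of these 200 genes 138 had a larger log2 fold change than CCL20, so its level does not by itself bear out the labels. With a correction for mRNA length, the log2 fold change of CCL20 was 0.06 with an SE of 0.24, and the call ended (edgeR adjusted p = 0.913). The call also ended on a TPM scale (0.47, edgeR adjusted p = 0.172), and it stayed with DESeq2 (0.95, DESeq2 adjusted p = 0.00345). Without control replicates 1 and 2 the log2 fold change of CCL20 was 1.09 and 0.82. Without overexpression replicates 1 and 2 it was 0.78 and 1.12. With 1 library left in a group, the test takes its spread from the other group's pair alone. The overexpression pair varied more than the control pair (chi-square per gene 41.51 against 7.18), so the calls of CCL20 in these fits are not compared. CCR6, the receptor of CCL20, had no value in the tables analysed here. Each of the 29437 listed genes had a read in some library, so CCR6 may be missing because it had no reads.

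**Figure D1:**
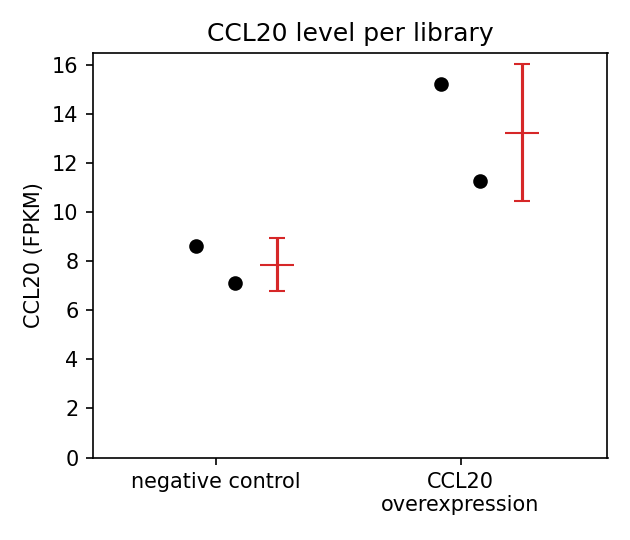
CCL20 level in FPKM (vertical axis) in each of the 4 libraries, by group (horizontal axis); black points are libraries, and the red mark and bar are the mean and SD. The overexpression libraries, at 15.2 and 11.3 FPKM, lie above the control libraries, at 8.62 and 7.10 FPKM.

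Between the groups, 2010 genes were higher and 1905 were lower with CCL20 overexpression among 12168 genes tested. The direction followed mRNA length. The higher coding genes had a median mRNA length of 1404 nt and the lower ones 5848 nt, against 2998 nt for all tested coding genes. In the tenth of coding genes with the shortest mRNAs, the median log2 fold change was 0.98, with 774 genes higher and 12 lower. In the tenth with the longest mRNAs it was -0.73, with 15 higher and 649 lower. Across the coding genes, which are not independent replicates, the Spearman correlation of log2 fold change with mRNA length was -0.73. The overexpression replicates also differed by length, with a correlation of -0.30 for replicate 2 minus replicate 1, and of -0.36 over coding genes with a mean FPKM of at least 20. For the controls these were -0.15 and -0.06, with a slope of -0.0038 (SE 0.0037) per doubling of mRNA length at that FPKM. The mean gene length per counted read was 6226 and 6130 nt in the control libraries and 5313 and 5013 nt in the overexpression libraries.

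The counts above are from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. With the mRNA length correction 385 genes were higher and 336 lower, of which 507 were called in the same direction without it. The number of calls fell to 650 without control replicate 1 and to 989 without control replicate 2, and rose to 7579 without overexpression replicate 1 and to 6413 without overexpression replicate 2. Of the 68 calls among the genes named by the rule other than CCL20, 38 ended without control replicate 1 and 27 without control replicate 2, of which 5 and 3 were among the 24 genes with the largest rises and falls. In each fit without a library the spread came from the pair of the other group. That pair varied more in the overexpression group than in the control, so these changes in calls do not show which library matters. The split depended on the scale. On a TPM scale, which moved the median log2 fold change of all genes to -0.49, 500 genes were higher and 4516 lower, and a limma test of log2(FPKM + 1) gave 1245 higher and 2608 lower with a median of -0.17. With pseudocounts of 0.1 and 0.5 the limma splits were 1176 to 2438 and 1221 to 2536. A correction for exonic length gave 874 higher and 489 lower in coding genes and 1143 higher and 709 lower over all gene types.

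**Figure D2:**
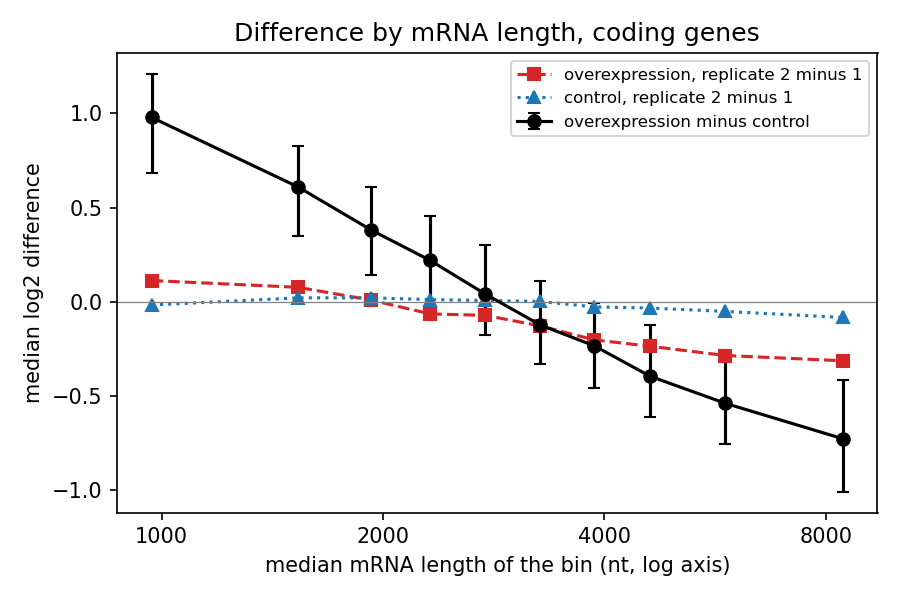
Median log2 difference (vertical axis) against the median mRNA length in nt (horizontal axis, log scale) of 10 bins of coding genes; black points with bars are overexpression minus control with the quartiles, and red squares and blue triangles are replicate 2 minus replicate 1 of the overexpression and control groups. The difference between groups goes from 0.98 in the shortest bin to -0.73 in the longest, and that between the overexpression replicates from 0.11 to -0.31.

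The 12 coding genes with the largest rises had mRNAs of 332 to 2047 nt, and 11 of them were under 1200 nt. They held 2 genes of mitochondrial ribosomal proteins, MRPL12 rising 3.61-fold from 5.75 ± 1.80 to 18.0 ± 5.68 FPKM and MRPL23 rising 3.41-fold from 13.2 ± 0.211 to 38.7 ± 9.27 FPKM (SD, n = 2 each). DPM3, a subunit of dolichol-phosphate mannose synthase, rose 3.79-fold and EXOSC4, a subunit of the RNA exosome, rose 3.42-fold. DEFB4B, a beta-defensin, rose 3.42-fold, SPRR1B, a precursor of the cornified envelope, rose 3.42-fold, and IL20RB, a receptor subunit for cytokines of the interleukin-20 family, rose 3.42-fold from 0.801 ± 0.213 to 2.40 ± 0.266 FPKM. The others were C6orf226, TMEM160, LY96, C4orf48 and CCDC167, with rises of 4.36-, 3.52-, 3.52-, 3.48- and 3.44-fold. The edgeR adjusted p of the 12 genes lay between 0.00433 and 0.0327. With the mRNA length correction, IL20RB (log2 fold change 1.49, edgeR adjusted p = 0.0305) and MRPL23 (0.80, edgeR adjusted p = 0.0353) were past the threshold; the other 10 were not, with corrected log2 fold changes of 0.76 to 1.13. With a correction for mRNA length, gene span and GC content, 7 of the 12 were past the threshold, adding DPM3, MRPL12, TMEM160, CCDC167 and EXOSC4 (edgeR adjusted p = 0.0145, 0.0203, 0.0145, 0.0051 and 0.0079). DEFB4B has a near-identical copy, so its value is uncertain.

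The 12 largest falls were in genes at 1.15 to 5.05 FPKM over the 4 libraries. BCL9L, a coactivator of beta-catenin, fell 6.95-fold from 8.98 ± 0.959 to 1.12 ± 0.213 FPKM, and NFAT5, a transcription factor of the osmotic stress response, fell 7.08-fold from 6.08 ± 0.533 to 0.757 ± 0.462 FPKM (SD, n = 2 each). ACER2, an alkaline ceramidase, fell 9.20-fold, and NNAT, the gene of neuronatin, fell 9.61-fold. ARHGAP5 fell 6.26-fold, and POMK, a kinase of the O-mannose glycan of dystroglycan, fell 6.11-fold. POTEF, ANKRD61, PCDHGC3, KLHL11 and RNF169 fell 15.7-, 7.48-, 7.26-, 7.05- and 6.48-fold. DEFB131B had 22 and 8 counts in the control libraries and 0 in both overexpression libraries, which makes it at least 4.78-fold lower with a floor of 3 counts per library. The folds of POTEF, NNAT, ACER2, ANKRD61, KLHL11 and POMK rest on 2 to 33 counts in each overexpression library. The edgeR adjusted p of the 12 genes lay between 0.00341 and 0.0283, and with the mRNA length correction all 12 were past the threshold. DEFB131B and POTEF have near-identical copies and PCDHGC3 shares exons with its cluster, so their values are uncertain.

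Of 33 gene lists tested, 4 were higher and 1 was lower with CCL20 overexpression. Ribosomal proteins rose, with 38 of 40 members higher and 0 lower, a median log2 fold change of 1.19 and a median mRNA length of 1036 nt (camera adjusted p = 1.47e-19; adjusted p = 0.674 with an estimated correlation). Adjusted over the list alone, 38 were higher and 0 lower. RPS12 rose 2.60-fold from 1142 ± 74.5 to 2577 ± 139 FPKM and RPS19 2.83-fold from 202 ± 0.715 to 494 ± 56.8 FPKM (SD, n = 2 each), and RPS14 and RPS27 rose 2.54- and 2.57-fold. The many processed copies of these genes make single values uncertain. The nuclear-encoded genes of oxidative phosphorylation rose in 28 of 33 members and fell in 0, with a median log2 fold change of 1.10 and a median mRNA length of 1153 nt (camera adjusted p = 1.12e-11; adjusted p = 0.674 with an estimated correlation), and adjusted over the list alone 29 were higher and 0 lower. COX6C rose 2.72-fold and NDUFS3 2.32-fold, COX7C 2.33-fold and COX5A 2.25-fold. With the mRNA length correction both lists were past the threshold, with medians of 0.42 and 0.35 (camera adjusted p = 1.78e-11 and 1.8e-07; adjusted p = 0.608 for each with an estimated correlation), and 10 and 6 members were higher. None of the 8 genes named from these lists was among those 16: the corrected log2 fold changes of RPS12, RPS19, RPS14 and RPS27 were 0.41, 0.53, 0.38 and 0.34 (edgeR adjusted p = 0.141, 0.0586, 0.143 and 0.241). Those of COX6C, NDUFS3, COX7C and COX5A were 0.48, 0.38, 0.46 and 0.32 (edgeR adjusted p = 0.143, 0.190, 0.105 and 0.268). With the correction for mRNA length, span and GC, RPS19, RPS14, COX6C, NDUFS3 and COX5A were past the threshold (edgeR adjusted p = 0.0080, 0.0443, 0.0074, 0.0362 and 0.0359).

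Antigen presentation genes were higher in 12 of 20 members and lower in 1, NLRC5, with a median log2 fold change of 0.68 and a median mRNA length of 1542 nt (camera adjusted p = 0.00529; adjusted p = 0.674 with an estimated correlation), and adjusted over the list alone 13 were higher and 1 lower. PSMB8, a subunit of the immunoproteasome, rose 2.21-fold, and the class I genes HLA-F and HLA-B rose 2.06- and 1.80-fold, though reads of HLA genes can be shared. Keratinocyte differentiation genes were higher in 6 of 13 members and lower in 0, with a median of 0.94 and a median mRNA length of 1644 nt (camera adjusted p = 0.00684; adjusted p = 0.674 with an estimated correlation), and adjusted over the list alone 7 were higher and 0 lower. CSTA and CNFN, of the cornified envelope, rose 2.13- and 2.91-fold, and CALML3 and KRT17 rose 2.05- and 1.92-fold. Basal keratinocyte and hemidesmosome genes were lower in 10 of 19 members and higher in 1, CD151, with a median of -0.55 and a median mRNA length of 5147 nt (camera adjusted p = 0.0114; adjusted p = 0.674 with an estimated correlation), and adjusted over the list alone 1 was higher and 11 lower. EGFR fell 2.10-fold from 91.2 ± 3.82 to 37.9 ± 4.94 FPKM (SD, n = 2 each), and PLEC, DST and LAMA3, which anchor basal cells to the basement membrane, also fell, PLEC from 51.2 to 22.1 FPKM, DST 1.86-fold and LAMA3 1.72-fold. NLRC5 and CD151 were named after their values were seen. With the mRNA length correction the calls of EGFR (log2 fold change -0.31, edgeR adjusted p = 0.207) and PLEC (-0.09, edgeR adjusted p = 0.849) ended, and DST and LAMA3 changed sign, to 0.0117 and 0.0174 (edgeR adjusted p = 0.975 and 0.971). CALML3 stayed past the threshold (edgeR adjusted p = 0.0200), and PSMB8, HLA-F, HLA-B, CSTA, CNFN and KRT17 did not (edgeR adjusted p from 0.114 to 0.607). With the correction for mRNA length, span and GC, PSMB8, HLA-F and HLA-B were past it (edgeR adjusted p = 0.0330, 0.0146 and 0.0175). With the mRNA length correction the medians of these 3 lists were 0.13, 0.28 and -0.01, and their calls ended (camera adjusted p = 0.891, 0.246 and 0.893). The camera test used a preset correlation between genes of 0.01, and with an estimated correlation 0 of the 33 lists passed. The test with an estimated correlation rests on 2 residual degrees of freedom. Oxidative phosphorylation genes also failed it, with an estimate of 0.0214 near the preset, so its failures say little about correlation between genes. For ribosomal proteins the estimate was 0.586. The call of the keratinocyte differentiation list also ended without overexpression replicate 2 (camera adjusted p = 0.105).

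**Figure D3:**
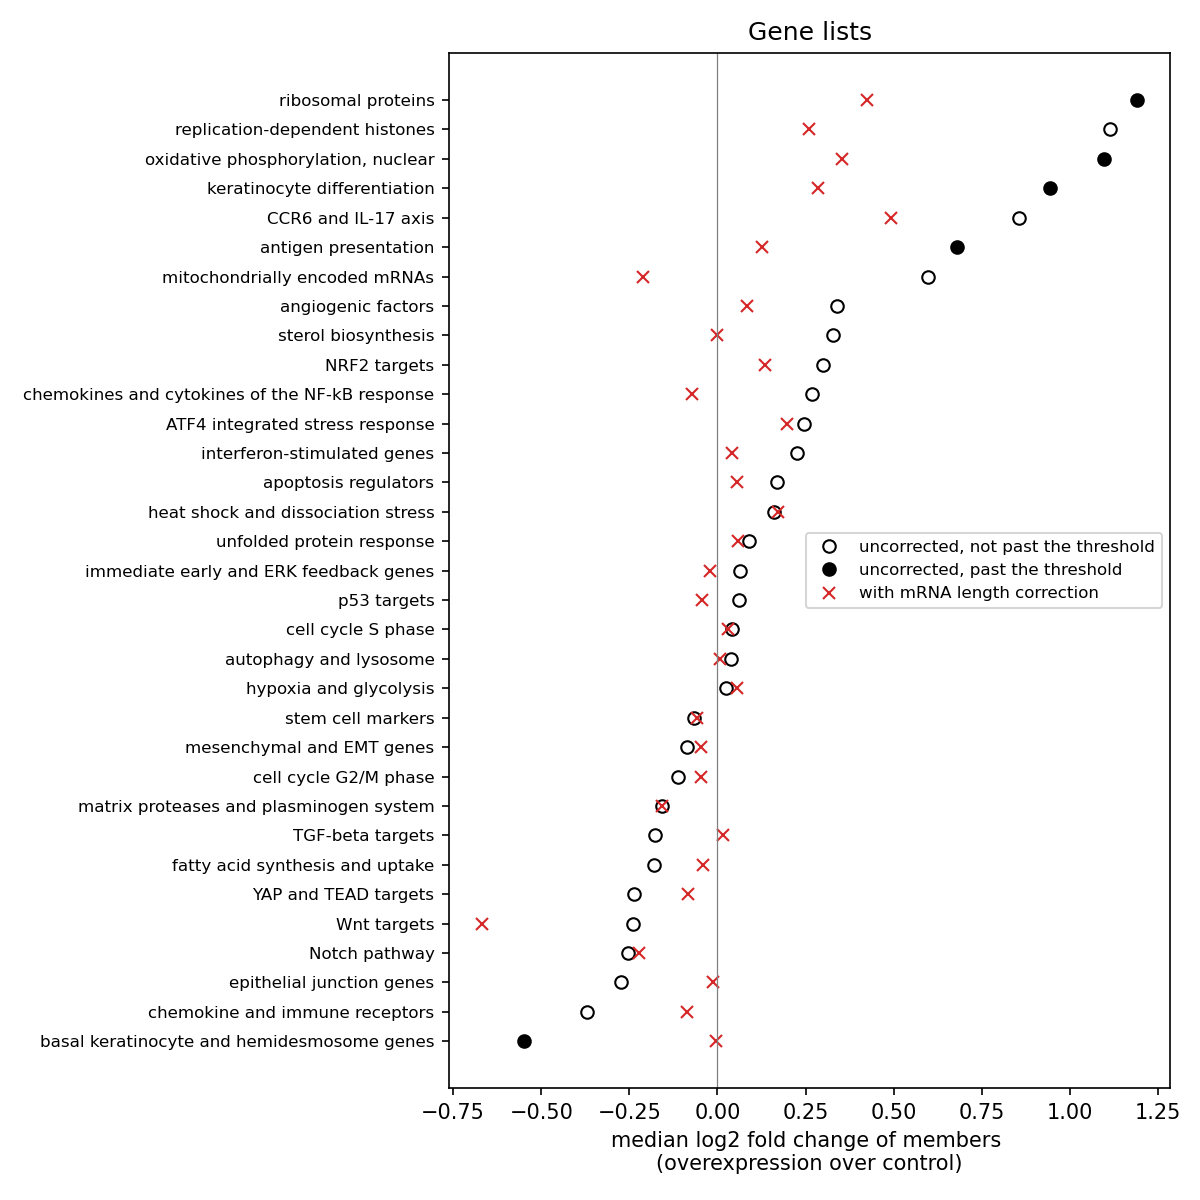
Median log2 fold change of the members of 33 gene lists (horizontal axis), overexpression over control; circles are without length correction, filled where the list passed camera's test, and red crosses are with the mRNA length correction. The medians of ribosomal proteins and basal keratinocyte genes go from 1.19 to 0.42 and from -0.55 to -0.01.

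At an adjusted p under 0.05 the lists of immune signalling did not pass. The genes of the CCR6 and IL-17 axis were higher in 5 of 9 members and lower in 0 (camera adjusted p = 0.0634), and SAA1 and LCN2 rose 2.96- and 1.93-fold. This list passed in some other settings, among them without control replicate 1 (camera adjusted p = 0.016). The median mRNA length of these members was 835 nt, and with the mRNA length correction SAA1 and LCN2 were not past the threshold (edgeR adjusted p = 0.102 and 0.941). Chemokines and cytokines of the NF-kB response were higher in 7 and lower in 4 of 30 members (camera adjusted p = 0.596), with CCL2 at 96.5 ± 13.6 FPKM in the control and 115 ± 22.1 with overexpression (SD, n = 2 each). Interferon-stimulated genes were higher in 9 and lower in 6 of 38 members (camera adjusted p = 0.388), and ISG15 and IFITM3 rose 2.83- and 2.32-fold without the correction and were not past the threshold with it (log2 fold change 0.54 and 0.29, edgeR adjusted p = 0.0676 and 0.360). With the correction for mRNA length, span and GC, SAA1 and ISG15 were past it (log2 fold change 0.55 for each, edgeR adjusted p = 0.0277 and 0.0364). Chemokine and immune receptors were lower in 4 of 10 members and higher in 0 (camera adjusted p = 0.133), with OSMR falling 1.65-fold without the correction and not past the threshold with it (log2 fold change -0.23, edgeR adjusted p = 0.405).

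Among lists of growth and cell state, S phase genes were higher in 6 and lower in 6 of 34 members (camera adjusted p = 0.915), and genes of the G2/M phase were higher in 7 and lower in 7 of 34 (0.712). Apoptosis regulators were higher in 6 and lower in 2 of 30 (0.391), p53 targets higher in 3 and lower in 2 of 20 (0.847), and stem cell markers higher in 0 and lower in 2 of 11 (0.712). Immediate early and ERK feedback genes were higher in 2 and lower in 3 of 30 (0.979), YAP and TEAD targets higher in 1 and lower in 7 of 19 (0.0634), TGF-beta targets higher in 3 and lower in 4 of 18 (0.665), Wnt targets higher in 0 and lower in 2 of 6 (0.665), and the Notch pathway higher in 2 and lower in 5 of 15 (0.198). CCND1, a cyclin and Wnt target, fell 1.91-fold from 56.2 ± 1.01 to 25.6 ± 3.68 FPKM (SD, n = 2 each), and was also past the threshold with the mRNA length correction (log2 fold change -0.61, edgeR adjusted p = 0.0451). Mesenchymal genes were higher in 1 and lower in 3 of 18 (0.418), epithelial junction genes higher in 2 and lower in 7 of 26 (0.185), matrix proteases and the plasminogen system higher in 2 and lower in 3 of 17 (0.665), and angiogenic factors higher in 2 and lower in 1 of 13 (0.774). The YAP and TEAD list passed, lower, without control replicate 1 and without overexpression replicate 1. Values in parentheses without a name are camera adjusted p.

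Among lists of metabolism and stress, NRF2 targets were higher in 9 and lower in 2 of 25 members (camera adjusted p = 0.0599), with the ferritin gene FTL and the thioredoxin gene TXN rising 2.01- and 2.28-fold. The list passed without control replicate 1 and without overexpression replicate 2 (camera adjusted p = 0.016 and 0.0182). The calls of FTL and TXN ended with the mRNA length correction (log2 fold change 0.13 and 0.32, edgeR adjusted p = 0.679 and 0.384). Hypoxia and glycolysis genes were higher in 5 and lower in 3 of 30 (camera adjusted p = 0.712), sterol biosynthesis genes higher in 6 and lower in 4 of 23 (0.647), and fatty acid genes higher in 1 and lower in 4 of 19 (0.185). The unfolded protein response was higher in 4 and lower in 3 of 21 (0.712), the ATF4 integrated stress response higher in 5 and lower in 4 of 29 (0.299), heat shock genes higher in 4 and lower in 0 of 15 (0.133), and autophagy and lysosome genes higher in 6 and lower in 1 of 28 (0.647). Mitochondrially encoded mRNAs were higher in 3 and lower in 2 of 13 (0.198), and MT-CO2 rose 1.87-fold, with a log2 fold change of -0.07 with the mRNA length correction. The mitochondrial list passed without overexpression replicate 1 (camera adjusted p = 0.0421). Replication-dependent histone genes were higher in 1 and lower in 0 of 7 (0.133). Median and mean log2 fold change had opposite signs for S phase genes, 0.04 and -0.04.

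Markers of other cell types that the cultures could hold were also measured. FBLN1, the highest of the fibroblast markers, was at 5.79 ± 0.818 FPKM in the control and 5.60 ± 1.09 with overexpression. LCP1, the highest leukocyte marker, was at 12.2 ± 0.0422 and 8.14 ± 1.30 FPKM, and CDH5, the highest endothelial marker, at 8.39 ± 0.392 and 5.11 ± 0.116 FPKM (SD, n = 2 each). None of the 3 genes passed the test (edgeR adjusted p = 0.582, 0.113 and 0.0502). These lists had 2, 3 and 1 tested members and were not tested as sets.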

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

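The length corrections, limma on log2(FPKM + 1), edgeR's own filter and the restriction to coding genes were chosen after seeing the data. For each change below the cause was not tested, except that fewer libraries or a stricter threshold account for some. Leaving out a library gave 650 to 7579 genes past the threshold (318 to 3742 higher, 332 to 3837 lower) against 3915, with the lowest values without control replicate 1 and the highest without overexpression replicate 1; a lone library is then assumed to vary like the other group. CCL20 gave log2 fold changes of 0.78 to 1.12 and 5 to 8 lists passed; the keratinocyte differentiation list ended without overexpression replicate 2 (camera adjusted p = 0.105). It also ended with a mean FPKM of at least 5 (0.0837), and antigen presentation ended with quantile normalization (0.206). At least 2-fold changes left 1500 genes (825 and 675) and 2 lists. With the TPM scale 500 were higher and 4516 lower, CCL20 was at 0.47 and 9 lists passed. Higher genes numbered 1176, 1221 and 1245 with limma at pseudocounts of 0.1, 0.5 and 1, with 9 lists each. The lists numbered 11 with no filter, 10 with quantile normalization, 8 at an adjusted p under 0.1, and 0 with an estimated correlation. The 3 gained at 0.1 were NRF2 targets, the CCR6 and IL-17 axis and YAP and TEAD targets; these also passed with limma at each pseudocount, the TPM scale and without control replicate 1. Histones passed with limma, the TPM scale, quantile normalization and no filter. Quantile normalization further gained epithelial junction and G2/M genes, and no filter the NF-kB, ATF4 and heat shock lists. With fry they were 2, oxidative phosphorylation and apoptosis regulators (fry adjusted p = 0.0219 for each), so 1 of the 5 called lists stayed and ribosomal proteins did not (0.0646).

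Corrections gave, for total, higher and lower genes, CCL20 and lists: mRNA length 721, 385, 336, 0.0582 and 2; longest mRNA length 777, 432, 345, 0.0543 and 2; exonic length in coding genes 1363, 874, 489, 0.20 and 3; exonic length over all gene types 1852, 1143, 709, 0.49 and 5; mRNA length, span and GC 2524, 1401, 1123, 0.0646 and 2; longest mRNA length, span and GC 2651, 1487, 1164, 0.0479 and 2; exonic length, span and GC over all gene types 4515, 2484, 2031, 0.48 and 4. In the last of these 7 CCL20 was past the threshold (edgeR adjusted p = 0.037), and in the other 6 it was not. The lists that passed were not all those called without a correction. Exonic length over all gene types kept 3 of the called lists and gained the CCR6 and IL-17 axis and, lower, YAP and TEAD targets. YAP and TEAD targets were also gained, lower, with exonic length in coding genes. Exonic length, span and GC over all gene types gained them too, with the Notch pathway, both lower. Over the alternatives with all 4 libraries the adjusted p of CCL20 ranged from 7.44e-05 (edgeR, replicate block) to 0.916 (edgeR, longest mRNA length correction). Its direction did not change in any alternative.

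Replicate numbers are shared by the groups but nothing pairs them; deviations of same-numbered libraries had a correlation of 0.265 across genes. With the replicate block 5758 genes passed (2840 higher, 2918 lower).

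Of the 68 calls among named genes other than CCL20, 38 and 27 ended without control replicates 1 and 2 and 0 without either overexpression replicate; 20 ended on the TPM scale, 15 with quantile normalization, 6 or fewer with each other setting that has no length correction, and 6 to 52 with the length corrections. Of the named genes and lists, these changed direction where either value was past the threshold. With quantile normalization, CALR was at -0.74, SLC3A2 at -0.28, CYR61 at -0.65, MT-CO1 at -0.41 and HSP90AB1 at -0.57, and hypoxia and glycolysis genes were lower with an adjusted p of 0.0154 (-0.0154 when signed). In the order mRNA length, exonic length, mRNA length with span and GC, longest mRNA, and longest mRNA with span and GC, MT-CO2 was at -0.0665, -0.0282, -0.104, -0.067 and -0.0923. DST was at 0.0117 with mRNA length, 0.0946 with exonic length, 0.19 with exonic length over all gene types, 0.00318 with mRNA length, span and GC and 0.14 with exonic length, span and GC. LAMA3 was at 0.0174 with mRNA length, and at 0.0934 and 0.0579 with mRNA and longest mRNA length with span and GC. PCNA was at -0.14 with exonic length, -0.0523 with mRNA length, span and GC, -0.0152 with longest mRNA length and -0.0789 with longest mRNA length, span and GC. With mRNA and longest mRNA length, each with span and GC, CCL2 was at -0.57 and -0.58, GADD45A at -0.00167 and -0.0423, CALR at -0.38 and -0.43, and CD44 at 0.48 and 0.46. With exonic length, span and GC over all gene types CALR was at -0.36 and CD44 at 0.41. With longest mRNA length, span and GC LCN2 was at -0.00186 and UBE2C at -0.0148. A further 252 sign changes were between values of which neither passed.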

Other observations

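Of the tests here, the slope at high expression and the number of lists that stay called were fixed before their results were seen; the others were chosen after the result was seen. The group is the same for both libraries of a side, so a response of the cells to CCL20 stays open for each pattern and untested.

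Long genes were lower and short genes higher with overexpression. An even background such as genomic DNA in the control libraries would fade at high expression, but over coding genes with a mean FPKM of at least 20 the slope was -0.457 per doubling of exonic length (SE 0.0112). Unspliced RNA acting by gene span would leave little slope at equal span, but it was -0.359 (SE 0.0072). A library property that acts by transcript length, such as RNA integrity or fragment selection, may contribute: the 2 overexpression libraries, which share their treatment, also differed from each other by length, with a Spearman correlation of -0.227. That correlation is weaker than the -0.62 between groups, so it leaves open how much of the trend has this source. At equal gene span the exonic slope between the overexpression libraries went from -0.112 to -0.0225 (SE 0.0057). Between groups it went from -0.445 to -0.359. On mRNA length the slope between the overexpression libraries went from -0.134 to -0.0761 (SE 0.0049) at equal span. At equal mRNA length the slope per doubling of gene span was -0.0565 (SE 0.0026) between these 2 libraries and -0.0597 (SE 0.0029) between groups. Both differences thus went with gene span to a like extent, beside a weaker length slope between the 2 overexpression libraries.

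CCL20 was 1.94-fold higher with overexpression. Its log2 fold change lay at the percentile of 59.5 among the 200 coding genes nearest in exonic length and at 31.0 among the 200 nearest in mRNA length, so a rise of this size may come from the length trend alone. Reads from a viral insert, some of which counting may miss, were not analysed apart from those of the gene, so the level of the introduced transcript stays open.

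With the length correction in use when the prediction was written, 3 of the 5 called lists stayed past the threshold, between the bounds set for and against the trend, and with the mRNA length correction 2 stayed. Among matched random lists, ribosomal proteins and oxidative phosphorylation genes lay at percentiles of 100.0 and 100.0 with all members and at 99.43 and 97.62 with members under 1200 nt (92.31 for ribosomal proteins with related genes in the pool), and both stayed called in all 7 corrections at the preset correlation, which argues against the trend as their whole cause. That argument is weak. The random lists were drawn gene by gene, so the percentiles do not allow for members that vary together or for the spread between libraries. The 7 corrections were run on the same 4 libraries and are not separate evidence. The preset correlation of 0.01 lies far below the 0.586 estimated for ribosomal proteins, though near the 0.0214 for oxidative phosphorylation genes. With an estimated correlation neither list passed camera's test (adjusted p = 0.674, and 0.608 with the mRNA length correction). That test rests on 2 residual degrees of freedom and passed 0 of the 33 lists, so it cannot decide. An earlier form of the matched test gave the trend as an explanation for both lists. It was replaced after its result was seen, because it departed from its written rule. Antigen presentation lay at 77.63 and its call ended with the mRNA length correction (median from 0.68 to 0.13). Its rise may therefore come from the trend. Of the 7 corrections, only exonic length over all gene types kept its call (camera adjusted p = 0.0446). Keratinocyte differentiation at 99.81 and basal keratinocyte genes at 1.29 lay outside the central range of matched lists, as did the uncalled G2/M phase at 0.35, mitochondrially encoded mRNAs at 0.95 and sterol biosynthesis at 97.57, while the correction ended both calls (medians from 0.94 to 0.28 and from -0.55 to -0.01), so for these 2 lists the trend and a change of their own cannot be told apart.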
